A study of Homo sapiens with 6 samples.

How the data were processed

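RNA sequencing libraries from MOLT-3 cells were compared between 2 groups, DMSO and compound E, with 3 libraries in each, as assigned by the treatment and the title in the labels. Per the labels, messenger RNA was taken from total RNA with oligo-dT beads and made into libraries with an NEBNext Ultra kit. The dose of compound E and the length of the treatment are not given in the sources used here. The submitters' processing notes name HISAT2 2.0.5, an aligner, featureCounts 1.5.0-p3, a read counter, and DESeq2 1.16.1, a package for differential expression, with no role or order. Genome build, annotation, treatment of reads with several matches and use of the strand are not given in the sources used here, so values of overlapping genes, of genes with near-identical copies and of antisense genes are uncertain.

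The deposited count table held whole-number read counts per gene for the 6 libraries, which the authors had not normalised. A second table deposited by the authors held FPKM values. In it the ratio of count to FPKM times gene length gave 1 divisor per library, which equalled the library's DESeq2 size factor times the geometric mean of the totals, so each FPKM is a count divided by gene length and by a scaled depth. All 58735 gene identifiers of the tables had the same start, end, strand and name in GENCODE release 29, and coordinates are therefore given on GRCh38, the build of that release. The totals per library were 17316138 to 19845114 counts, and 25229 genes had 0 counts in every library.

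Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 16926, libraries were scaled by TMM, and compound E was compared with DMSO by the quasi-likelihood F-test with the treatment as the only term. P-values were adjusted by Benjamini-Hochberg over all tested genes, and genes with an adjusted p under 0.05 were called. The standard error of a log2 fold change was taken as its size divided by the square root of F. The common dispersion was 0.00074, a biological coefficient of variation of 2.72%. Shares of counts were compared by exact permutation tests.

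Lists of genes, 36 in number, were written before the data were examined, from textbook knowledge and not from these samples, and the 34 with at least 5 tested members were tested with camera of limma 3.58.1. It used log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and its p-values were adjusted by Benjamini-Hochberg over the lists. Log2 values were computed here, since the tables deposited by the authors hold no log2 values. The text names 13 design genes, the 8 largest rises and the 8 largest falls among called protein-coding genes with a mean of at least 5 CPM and groups that do not overlap, and in each list up to 4 called members with the smallest p. Some genes that the rule takes are not reported here. That rule was also fixed before the data were examined. The other members named in the account of a list, which are the exceptions to its direction and further examples, and all genes of the closing observations outside the rule were chosen after their values were seen.

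The analysis was tested on simulated counts for 16926 genes with the means and library sizes of these samples, in which 50 genes were changed at each of 4 fold sizes. It recovered 48% of the genes changed 1.2-fold, 62% at 1.5-fold, 76% at 2-fold and 94% at 4-fold, and 5.39% of all calls were false. Far fewer genes were changed there than were called in the data. The adjustment was therefore stricter in the simulation, and recovery in the data may differ. A list with shifted members was called and 0 lists without any were called. Counts were drawn for each gene independently, so false calls of lists with correlated members could not be measured there.

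Alternatives chosen before the data were examined were other scalings (size factors by RLE, library size alone, upper quartile), no filter and a stricter filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, a correction for gene length with and without that block, protein-coding genes alone, limma on log2 FPKM with pseudocounts of 1 and 0.1 and without a filter, and each library left out in turn. For the lists they were camera with an estimated correlation, fry, the replicate block, other scalings, the stricter filter, FPKM and the left-out libraries. A correction for GC content and a fit without mitochondrial genes were added after the data were seen. The figures were drawn with matplotlib 3.10.9. No library was left out of the reported comparison, and the reads were not used here.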

Results

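Gene expression was measured by RNA sequencing of polyadenylated RNA in MOLT-3 cells, an established human cell line of T-cell acute lymphoblastic leukaemia. Of the 6 libraries, 3 came from cells given the solvent DMSO and 3 from cells given compound E, a gamma-secretase inhibitor that blocks the cleavage by which NOTCH receptors release their active intracellular part. The deposited count table held 58735 genes, with total counts of 19309393, 19845114 and 17316138 in DMSO replicates 1 to 3 and of 18213847, 18154037 and 18973990 in compound E replicates 1 to 3. Between 26408 and 27576 genes had a count in each library, and MT-CO1 took the largest share of counts, at 1.19% ± 0.00955 (SD, n = 3) with DMSO and 1.05% ± 0.0312 (SD, n = 3) with compound E. Values per gene are CPM, counts scaled to a common library size, after TMM scaling, given as mean ± SD over the 3 libraries of a group, and fold changes are compound E over DMSO. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

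Compound E was compared with DMSO to search for genes under the control of NOTCH1 that could bear on how these leukaemia cells respond to chemotherapy, and the title of the series names PREX2 and AKT. The largest falls among the genes of the design were in direct NOTCH targets. HES4, a transcriptional repressor of the Hairy/E(spl) family, fell 29.8-fold from 79.7 ± 5.14 to 2.67 ± 0.787 CPM, and DTX1, a ubiquitin ligase of the NOTCH pathway, fell 24.3-fold from 172 ± 6.86 to 7.06 ± 1.03 CPM (SD, n = 3 per group). PREX2, a guanine nucleotide exchange factor for RAC, rose 4.92-fold from 19.7 ± 0.693 to 97.0 ± 5.60 CPM. AKT1, the kinase named by the title, rose 1.17-fold from 194 ± 10.7 to 226 ± 9.36 CPM, and NOTCH1 itself rose 1.11-fold from 939 ± 16.3 to 1046 ± 31.7 CPM.

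Other targets of NOTCH1 fell as well. NOTCH3 fell 8.19-fold, from 302 ± 3.82 to 36.9 ± 1.85 CPM, and IL7R, the interleukin-7 receptor alpha chain, fell 5.39-fold, from 36.6 ± 1.76 to 6.77 ± 0.903 CPM. HES1, the repressor that relays much of NOTCH signalling, fell 4.46-fold, from 39.9 ± 2.81 to 8.92 ± 1.10 CPM, and IGF1R, the receptor of insulin-like growth factor 1, fell 2.77-fold, from 127 ± 2.17 to 46.0 ± 3.20 CPM. MYC fell 1.79-fold, from 393 ± 9.12 to 219 ± 5.67 CPM, and PTCRA, the pre-T-cell receptor alpha chain, fell 1.62-fold, from 44.0 ± 1.12 to 27.2 ± 1.26 CPM. NRARP, also a design gene, had too few counts to be tested, with 0, 2 and 1 counts in the DMSO libraries and 6, 0 and 7 in the compound E libraries.

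The 11 design genes described here with a test each passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over 16926 genes. The log2 fold changes with their standard errors and adjusted p from edgeR were -4.90 ± 0.0916 (adjusted p = 1.37e-33) for HES4, -4.60 ± 0.0601 (6.19e-39) for DTX1, -3.03 ± 0.0373 (1.01e-39) for NOTCH3 and 2.30 ± 0.0530 (1.50e-30) for PREX2. For the smaller changes they were 0.16 ± 0.0248 (adjusted p = 2.14e-06, edgeR) for NOTCH1 and 0.22 ± 0.0344 (1.33e-06) for AKT1. The genes lie on GRCh38 at chromosome 1, 998962 to 1000172, minus strand (HES4, ENSG00000188290), chromosome 12, 113056709 to 113098028, plus strand (DTX1, ENSG00000135144), and chromosome 19, 15159038 to 15200981, minus strand (NOTCH3, ENSG00000074181). PREX2 (ENSG00000046889) spans 67952118 to 68237030 on the plus strand of chromosome 8, NOTCH1 (ENSG00000148400) spans 136494433 to 136545786 on the minus strand of chromosome 9, and AKT1 (ENSG00000142208) spans 104769349 to 104795751 on the minus strand of chromosome 14. All counts are sums over a gene's exons, so they do not say which transcript of a gene changed.

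**Figure D1:**
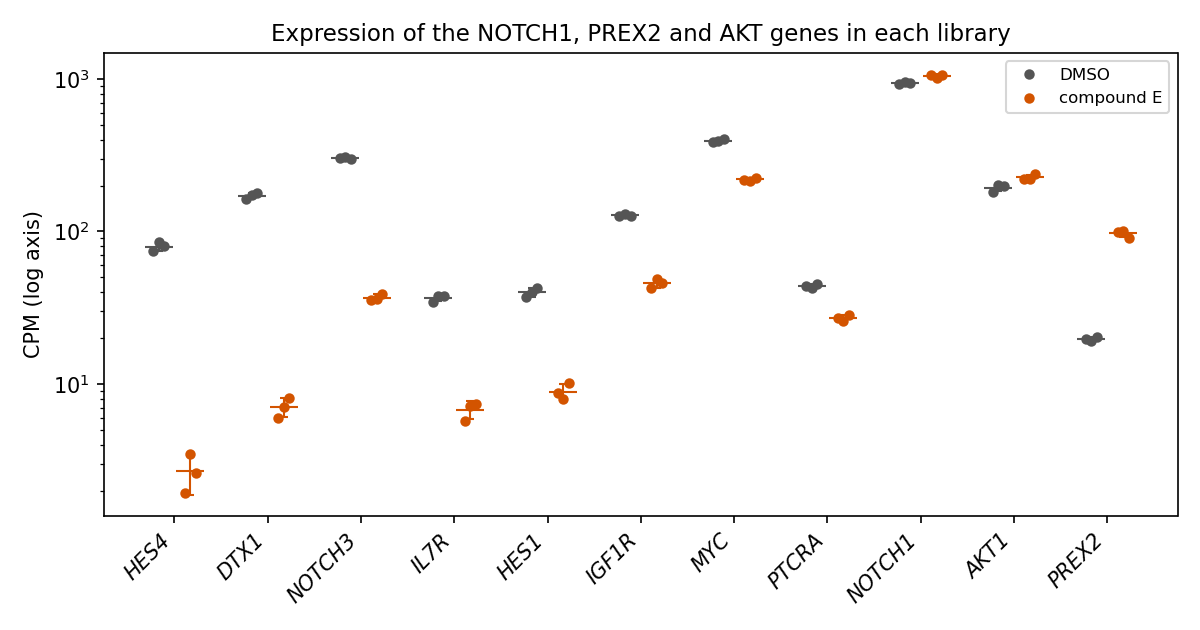
CPM of 11 tested design genes on a log axis, with 1 point per library, a horizontal bar at the group mean and error bars of 1 SD (n = 3 per group; DMSO grey, compound E orange). The groups do not overlap in any of the 11 genes, and PREX2, AKT1 and NOTCH1 are the genes with a higher mean with compound E.

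Over all genes, 6484 of 16926 tested genes (38.3%) changed, 3206 upwards and 3278 downwards, at a Benjamini-Hochberg adjusted p under 0.05 in the edgeR quasi-likelihood test. Most changes were small, with a median of 1.22-fold among the changed genes and 2928 of them under 1.2-fold. At 2-fold or more, 649 genes changed, of which 203 rose and 446 fell. Among all tested genes, 46.8% had every library of 1 group above every library of the other, where chance gives 10%. The share was 94.4% among the changed genes, which were selected by the same difference, so it adds no separate support. Of the protein-coding genes, 5667 of 12664 tested changed, and of the 2097 tested lincRNA and antisense genes 145 rose and 245 fell.

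The protein-coding genes with the largest rises, among those with a mean of at least 5 CPM and no overlap between the groups, were led by RASD1, a RAS-related GTPase induced by dexamethasone, which rose 7.28-fold from 3.83 ± 0.578 to 27.8 ± 2.87 CPM. MME, the surface peptidase CD10 of lymphoid progenitors, rose 6.04-fold from 1.79 ± 0.0731 to 10.9 ± 1.86 CPM, and PREX2 came next. Behind it were SHANK1, a scaffold protein of synapses, at a log2 fold change of 2.23 ± 0.106 (SE), KREMEN2, a receptor that dampens WNT signalling, at 2.20 ± 0.0753, the progenitor marker CD34 at 1.97 ± 0.144, PI16, a peptidase inhibitor, at 1.95 ± 0.0672 and the kinase SGK1 at 1.78 ± 0.145. Behind HES4 and DTX1, the largest falls were in the cytokine IL4 (15.8-fold, from 10.4 ± 0.931 to 0.648 ± 0.323 CPM) and SLC7A11, the cystine transporter (12.5-fold, from 86.9 ± 3.46 to 6.93 ± 0.623 CPM). NRXN3, a neurexin, fell to a log2 fold change of -3.46 ± 0.113 (SE), SLC6A9, a glycine transporter, to -3.36 ± 0.0973, the sodium channel gene SCN2A to -3.35 ± 0.0844 and the myosin gene MYO7B to -3.31 ± 0.0389. In these 16 genes the largest edgeR adjusted p (Benjamini-Hochberg) was 3.90e-13, for SGK1.

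**Figure D2:**
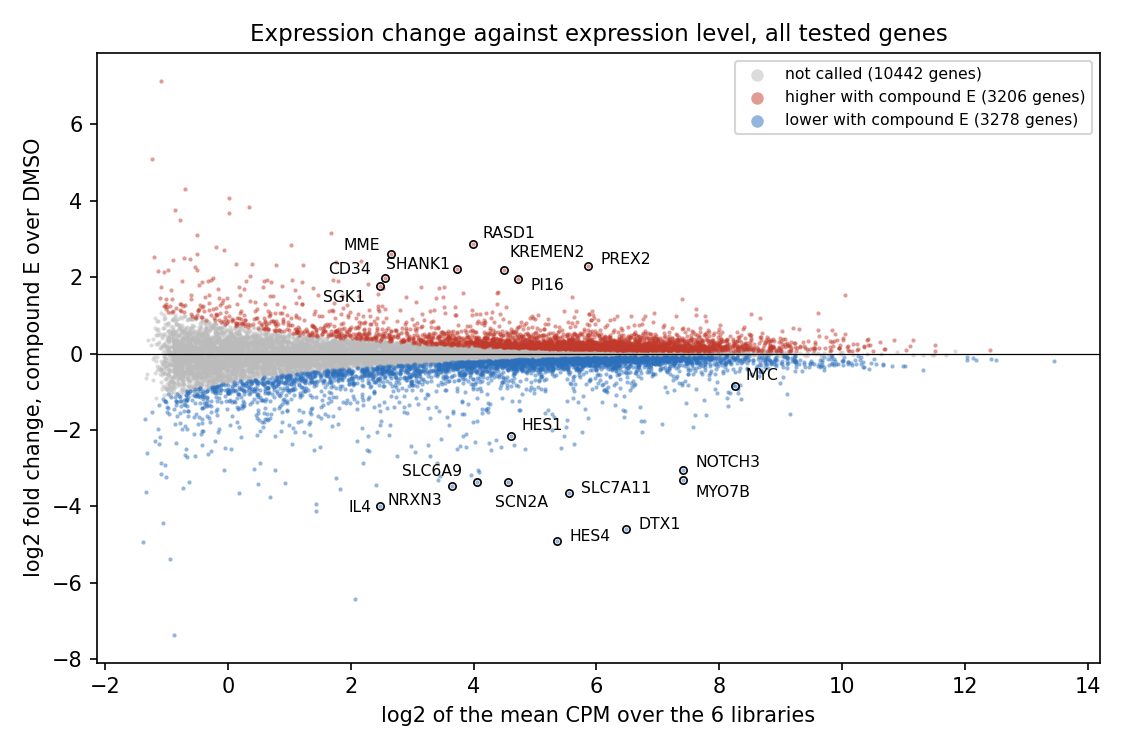
Log2 fold change of compound E over DMSO against the log2 of the mean CPM over the 6 libraries, with 1 point for each of 16926 tested genes (red, 3206 genes called higher; blue, 3278 called lower; grey, not called). Circles mark the 8 largest rises and the 8 largest falls by the naming rule and NOTCH3, HES1 and MYC; the falls to HES4 and DTX1 reach further from 0 than the rises to RASD1 and MME.

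Gene lists fixed before the data were examined were tested with camera, which compares a list with all other genes. Of 34 lists with at least 5 tested members, 11 were called at a Benjamini-Hochberg adjusted p under 0.05, 8 upwards and 3 downwards, and 6 of the 11 were also called with an estimated correlation. Counts of members are those called by edgeR over all genes; where no second count is given, the count adjusted over the list alone was the same.

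The 3 lists that fell were the NOTCH targets, the amino acid response and the ribosomal proteins. Of 16 tested NOTCH targets 13 fell and 2 rose (14 and 2 adjusted over the list alone), with a median log2 fold change of -1.79 (camera adjusted p = 8.84e-18; adjusted p = 0.0452 with an estimated correlation). RHOU, an atypical small GTPase, fell by 2.36 on the log2 scale beside HES4, DTX1 and NOTCH3, the 2 that rose were NOTCH1 (0.16) and the cyclin gene CCND3 (0.20), and HEYL, at -0.68, did not pass over all genes. The targets HES5, HEY1 and HEY2 had at most 3 counts in any library and were not tested.

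The amino acid response list holds genes driven by ATF4 when amino acids run short, and 28 of its 30 tested members fell, 21 of them at least 2-fold, while 1 rose. Its median was -1.40 (camera adjusted p = 1.51e-46; adjusted p = 0.00687 with an estimated correlation). The log2 fold change was -1.57 for SLC7A5, the large neutral amino acid transporter, -1.93 for PSAT1, of serine synthesis, -1.59 for MTHFD2, of mitochondrial folate metabolism, and -3.65 for SLC7A11, all called lower. DDIT4, an inhibitor of mTORC1, rose by 0.38, and WARS, at -0.09, did not pass.

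Ribosomal protein genes fell together by a small amount. Of 75 tested, 70 fell and 0 rose (71 and 1 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 3.76e-35; adjusted p = 0.0285 with an estimated correlation). RPL12 fell 1.36-fold, from 696 ± 8.16 to 511 ± 10.7 CPM, and RPS2, RPS3 and RPL3 fell with log2 fold changes of -0.40, -0.36 and -0.33. Many of these genes have processed pseudogenes, and how the authors counted reads shared with them is not given in the sources used here.

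Among the lists that rose, the mitosis and G2/M genes did so without exception. All 34 tested members rose, with a median of 0.39 (camera adjusted p = 2.52e-31; adjusted p = 0.0355 with an estimated correlation). CDC20, the activator of the anaphase-promoting complex, rose 1.77-fold from 87.6 ± 3.82 to 155 ± 7.41 CPM, and DLGAP5, CCNB2 and KIF20A rose by 0.78, 0.75 and 0.75 on the log2 scale. Genes of DNA replication and G1/S were split, with 10 of 36 higher and 14 lower (11 and 14 adjusted over the list alone; camera adjusted p = 0.914). In that list E2F2 (0.67), CCNE2 (0.59) and RRM2 (0.47) rose and the licensing factor CDT1 (-0.52) fell. Of 13 G1 cyclins and CDK inhibitors 4 rose, with CDKN2D at 1.06 and CDKN2C at 0.58, and 5 fell, with CCND2 at -1.84 and RB1 at -0.51 (camera adjusted p = 0.928). Among 12 tested replication-dependent histones, whose mRNAs mostly lack poly(A), 1 rose, HIST1H2AG at 0.58, and 0 did so adjusted over the list alone (camera adjusted p = 0.619). HIST1H2AG lost its call with DESeq2 (adjusted p = 0.156), with limma on FPKM (0.141 to 0.271) and in edgeR without DMSO replicate 1 (0.227), compound E replicate 1 (0.083) or compound E replicate 2 (0.104).

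Genes of the thymocyte stages, which mark steps of T-cell development, rose in 23 of 29 tested members and fell in 3, with a median of 0.49 (camera adjusted p = 7.91e-13; adjusted p = 0.0187 with an estimated correlation). RAG1, of the recombinase that joins receptor gene segments, rose 2.90-fold from 546 ± 8.09 to 1583 ± 34.9 CPM, and the chromatin organiser SATB1 (0.65) also rose. The members that fell were PTCRA (-0.69), CD1E (-0.67) and CCR9 (-0.22). Of 26 T-cell receptor complex and signalling genes 13 rose and 9 fell (camera adjusted p = 0.338), with THEMIS at 0.97, CD2 at 0.94 and PTPRC at 0.41 against CD7 at -0.73. T-ALL transcription factors went both ways, with 9 of 18 higher (10 adjusted over the list alone) and 7 lower (camera adjusted p = 0.525; median 0.11, mean -0.11). GATA3 (0.74), RUNX1 (0.45) and LEF1 (0.44) were among the higher ones, against MYC (-0.84). At 2-fold or more 0 members rose and 2 fell, and MYC was not among those 2.

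Cholesterol synthesis genes rose in 13 of 24 tested members and fell in 1, SREBF2 at -0.09 (16 and 1 adjusted over the list alone), with a median of 0.22 (camera adjusted p = 5.19e-06; adjusted p = 0.0376 with an estimated correlation). INSIG1, which holds back the processing of sterol regulatory proteins (0.50), and the lanosterol synthase gene LSS (0.34) rose.

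Another 5 lists were called upwards by camera and lost the call with an estimated correlation. With the stricter filter camera also lost the NF-kB (adjusted p = 0.0621), immediate early (0.0744), heat shock (0.0539) and anti-apoptotic (0.0508) lists. Of 18 genes of the glucocorticoid response 10 rose and 6 fell, with a median of 0.29 (camera adjusted p = 0.0108; adjusted p = 0.135 with an estimated correlation). SGK1, TXNIP (0.92) and FKBP5, a cochaperone of the glucocorticoid receptor (0.49), rose and IL7R fell. Among 15 NF-kB targets 8 rose (9 adjusted over the list alone) and 1 fell, CYLD at -0.19 (camera adjusted p = 0.0108, and 0.135 with an estimated correlation). TRAF1 (2.72), CD83 (0.82), TNFAIP3 (0.35) and LTB (0.30) were higher. TRAF1 was at low counts, from 0.249 ± 0.0814 to 1.67 ± 0.311 CPM, and LTB lost its call with limma on unfiltered FPKM (adjusted p = 0.0559). Immediate early genes rose in 13 of 21 members (14 adjusted over the list alone) and fell in 5 (camera adjusted p = 0.0406; adjusted p = 0.616 with an estimated correlation), with the nuclear receptor NR4A1 at 1.48, BTG2 at 0.87 and ATF3 at -0.89. Heat shock genes rose in 10 of 19 members and fell in 5 (camera adjusted p = 0.0352; adjusted p = 0.218 with an estimated correlation), and those that rose included HSP90B1 (0.61), HSPA5 (0.40) and DNAJA1 (0.35), while HERPUD1 fell (-0.76).

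For cell death and drug response the lists gave mixed counts. Of 9 anti-apoptotic genes 5 rose and 2 fell, with a median of 0.13 (camera adjusted p = 0.0453; adjusted p = 0.218 with an estimated correlation), and the call was lost without DMSO replicate 1 (camera adjusted p = 0.0619) and without compound E replicate 3 (0.056). BIRC5, which also belongs to mitosis (0.54), BIRC2 (0.48), BCL2L1 (0.39) and MCL1 (0.25) rose, and the 2 that fell were BCL2L2 (-0.56) and BCL2 (-0.31). The immediate early list also lost its call without compound E replicate 3 (camera adjusted p = 0.117). Pro-apoptotic genes rose in 7 of 20 and fell in 6 (camera adjusted p = 0.945; median 0.09, mean -0.11), with the BH3-only gene PMAIP1 falling 2.41-fold from 95.9 ± 1.91 to 39.9 ± 4.50 CPM, TNFRSF10B, a death receptor, at -0.75, and BMF (0.64) higher. Drug transport and metabolism genes rose in 8 of 24 (9 adjusted over the list alone) and fell in 5 (camera adjusted p = 0.23), where TOP2A, the target of anthracyclines (0.38), ABCC5 (0.39) and FPGS (0.30) rose and ASNS, asparagine synthetase, fell (-2.14). Of 24 p53 targets 5 rose, BTG2 and TP53INP1 (0.47) among them, and 7 fell, SESN2 (-2.16) and CCNG1 (-0.51) among them (camera adjusted p = 0.549). DNA repair genes rose in 6 of 32 and fell in 8 (camera adjusted p = 0.945), with LIG4 at 0.62, ATM at -0.52, XRCC2 at -0.37 and CHEK1 at -0.20.

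The PI3K and AKT pathway genes, which the title brings into question, did not move as a list, with 12 of 37 higher and 11 lower (camera adjusted p = 0.719). PREX2 rose most in it, and EIF4EBP1, the repressor of cap-dependent translation, fell 3.38-fold from 164 ± 5.95 to 48.5 ± 2.12 CPM, beside IGF1R and the phosphatase gene INPP5D (-0.38). FOXO targets, which AKT holds down, rose in 6 of 22 and fell in 5 (6 adjusted over the list alone; camera adjusted p = 0.928), with TXNIP and CCNG2 (0.27) higher and IL7R and BBC3 (-0.84) lower. Parts of the NOTCH pathway rose in 6 of 24 and fell in 3 (camera adjusted p = 0.632), with the sugar transferase MFNG (0.23) and the protease ADAM10 (0.17) higher. The largest changes among these parts were NOTCH3 at -3.03 and DLL4 at 2.60, the latter at low counts (0.195 to 1.22 CPM). With fry the list was called lower (adjusted p = 0.000584). MYC and nucleolar genes rose in 7 of 44 and fell in 11 (camera adjusted p = 0.427), with NPM1 at -0.43, HSPD1 at -0.37, FBL at -0.20 and CAD at -0.18.

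Energy metabolism lists were not called by camera. Glycolysis genes rose in 4 of 22 (5 adjusted over the list alone), with ALDOC at 1.30 and ENO2 at 0.30, and fell in 6, with PFKM at -0.47 and GPI at -0.25 (camera adjusted p = 0.619). Nuclear genes of oxidative phosphorylation rose in 6 of 43, including NDUFA1 and NDUFB3 (0.28 each) and NDUFA4 (0.24), and fell in 10 (camera adjusted p = 0.945; the median was 0.0041 and the camera direction downwards). Mitochondrially encoded mRNAs fell in 6 of 13 members and rose in 1, MT-ND3 at 0.10 (camera adjusted p = 0.215), with MT-CO1 and MT-CO2 at -0.18 and MT-ATP6 and MT-CO3 at -0.17. The calls of MT-CO2, MT-ATP6 and MT-CO3 were lost with DESeq2 (adjusted p = 0.238, 0.297 and 0.288) and with limma on FPKM (0.186 to 0.605), and that of MT-CO1 with limma on unfiltered FPKM (0.573). The share of counts on mitochondrial genes was 5.26% ± 0.0789 (SD, n = 3) with DMSO and 4.87% ± 0.313 (SD, n = 3) with compound E (2-sided exact permutation p = 0.2, where 0.1 is the smallest p the design allows). In the compound E libraries that share was 4.60%, 4.79% and 5.22%, and without compound E replicate 3 the mitochondrial list was called lower (camera adjusted p = 6.62e-06). Hypoxia response genes rose in 2 of 16, EGLN3 (1.49) and BNIP3 (0.34), and fell in 6, with VEGFA, the vascular growth factor, down 9.27-fold from 19.7 ± 0.627 to 2.11 ± 0.426 CPM and MXI1 at -0.45 (camera adjusted p = 0.488). Autophagy and lysosome genes rose in 9 of 32 and fell in 8 (camera adjusted p = 0.67), with ULK1 at 0.35, ATP6V0D1 at 0.34, LAMP1 at 0.23 and WIPI1 at -1.49.

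Immune lists and markers of other cell types were not called by camera. With fry the HLA (adjusted p = 0.0449), B-cell (0.0022), natural killer (0.00805) and fibroblast and epithelial (0.00805) lists were called lower. Interferon response genes rose in 5 of 27 and fell in 7 (6 and 8 adjusted over the list alone; camera adjusted p = 0.67), with MX1 (0.57) higher and OAS3 (-0.38) and IRF1 (-0.32) lower. HLA class I and II genes rose in 3 of 15 and fell in 3 (camera adjusted p = 0.67), with TAP1 at 0.33, HLA-B at -0.26 and HLA-E at -0.16. Of B-cell markers 5 were tested, of which CR2, also a NOTCH target (-2.43), fell and VPREB1 (0.73) rose (camera adjusted p = 0.619). Among 5 natural killer and cytotoxic markers KLRB1 (-1.22) and PRF1 (-0.67) fell (camera adjusted p = 0.435), and among 6 fibroblast and epithelial markers PDGFRB (-0.93) and THY1 (-0.33) fell (3 adjusted over the list alone; camera adjusted p = 0.549). KLRB1 lost its call with DESeq2 (adjusted p = 0.101), with limma on unfiltered FPKM (0.0961) and in edgeR without DMSO replicate 2 (0.133), and PDGFRB with limma on unfiltered FPKM (adjusted p = 0.0824). THY1 lost its call with DESeq2 (adjusted p = 0.0979), with limma on FPKM (0.102 to 0.228) and in edgeR without DMSO replicate 2 (0.0865) or compound E replicate 1 (0.101). Too few members were tested for a list test of myeloid markers (2 tested, AIF1 higher at 0.13) and of erythroid and megakaryocyte markers (3 tested, EPOR lower at -0.32, a call lost with DESeq2 at an adjusted p of 0.0769).

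**Figure D3:**
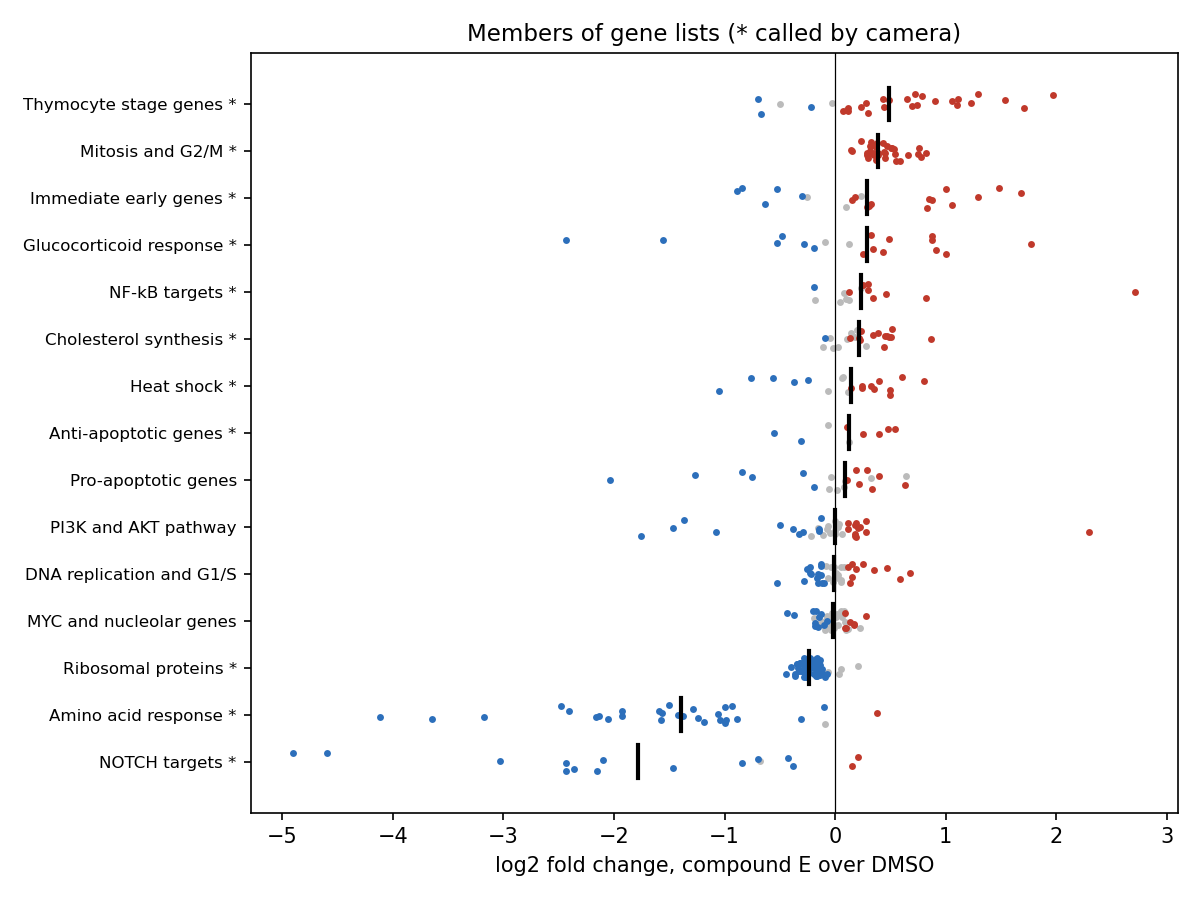
Log2 fold changes of the tested members of the 11 called lists (asterisk) and 4 uncalled lists, with 1 point per gene (red, called higher; blue, called lower; grey, not called) and a black bar at each list's median. The medians run from -1.79 for the NOTCH targets to 0.49 for the thymocyte stage genes, and the vertical scatter within a list has no meaning.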

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

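Except for the correction for GC content and the fit without mitochondrial genes, which were added after the data were seen, all settings were planned. Of the 6484 called genes, 0 were called in the opposite direction under any setting, and the count was 6420 to 6479 with other scalings, 6403 with limma-voom, 4517 with DESeq2, 6722 after GC correction and 6487 without mitochondrial genes. With limma on log2(FPKM + 1) without a filter it was 4002, for which the cause was not tested, and leaving out each library gave 5671 to 6068. The 649 genes changed at least 2-fold became 218 with the stricter filter and 430 among protein-coding genes alone, where fewer genes were tested. With limma on log2(FPKM + 1) there were 183 with a filter and 174 without one, and on log2(FPKM + 0.1) with the filter 436; these settings also changed the test, and the cause was not tested apart from the pseudocount. Leaving out each library gave 672 to 712. Of the 11 called lists, 6 were called with an estimated correlation and 7 with the stricter filter, which left 30 lists to test. With fry, which does not set a list against other genes, 21 were called. Leaving out each library gave 10 to 11 called lists; without compound E replicate 3, 9 of the 11 were among them, the anti-apoptotic (adjusted p = 0.056) and immediate early (0.117) lists being lost and the mitochondrial list gained. The glucocorticoid, NF-kB, immediate early, heat shock and anti-apoptotic lists account for every lost call of a list. Of 138 named genes, 0 reversed in 3017 pairs of gene and setting and 32 pairs lost the call, among them MT-CO1, MT-CO2, MT-CO3, MT-ATP6, HIST1H2AG, KLRB1 and THY1. The 23 uncalled lists changed direction in 16 of 292 pairs of list and setting and gained a call in 11, 10 of them with fry. Fry called lower the lists of NOTCH pathway parts, PI3K and AKT, p53 targets, hypoxia, HLA, and B-cell, natural killer and fibroblast markers. It called higher those of drug transport and of the T-cell receptor complex. With 17316138 to 19845114 counts per library, small changes can go uncalled, which limits what can be said of uncalled genes. The simulated recovery of 48% at 1.2-fold is only a rough measure of that limit, since far fewer genes were changed in the simulation than were called in the data.

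With the replicate number as a block, 6138 genes were called, 641 of them at 2-fold or more, and 10 lists, the anti-apoptotic list being lost (adjusted p = 0.0691 by camera). Together with the length correction the block gave 6251 and 644 genes. The deviations of libraries with the same number correlated at 0.0103, -0.0191 and 0.000118, and those with different numbers at -0.0202 to 0.0207. These values gave no sign that the numbers pair the samples. They cannot exclude pairing, since counting noise over all tested genes can hide a shared effect.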

Other observations

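The tests of other splits, of replicate spread, of gene length, of neighbouring genes and of tRNA synthetases were chosen after the result they concern had been seen, and the test of GC content was added after the data were seen. In the test of neighbouring genes, matching on coding status, the count of protein-coding pairs and the criteria for related pairs were added or widened after first results.

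The GIMAP genes, small GTPases of lymphocyte survival clustered on chromosome 7, were picked as a family after their values were seen, and 6 of 6 tested members fell. GIMAP2 fell 2.78-fold, from 54.7 ± 1.77 to 19.7 ± 1.26 CPM, and GIMAP1, GIMAP6 and GIMAP7 fell 4.45-fold, 2.71-fold and 4.73-fold (edgeR with Benjamini-Hochberg adjustment, largest adjusted p of the 4 = 8.55e-19). Of the thymocyte stage list, the coreceptor genes CD4 and CD8B rose 2.35-fold and 3.28-fold, to 18.1 ± 0.724 and 8.81 ± 0.334 CPM.

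At the T-cell receptor loci, TRAC, the constant gene of the alpha chain, rose 2.82-fold, from 25.6 ± 1.31 to 72.1 ± 4.05 CPM, and all 12 tested TRAJ joining segments rose at least 2-fold. TRGC1, a constant gene of the gamma chain, fell by 3.06 ± 0.402 (SE) on the log2 scale from 1.72 ± 0.450 CPM, and TRBC2, of the beta chain, rose 1.05-fold, from 2835 ± 14.8 to 2984 ± 101 CPM. TRBC1, the other constant gene of the beta chain, was at 2.01 ± 0.0824 and 2.54 ± 0.321 CPM and was not called. TSC22D3 (GILZ), a glucocorticoid target, fell 2.95-fold, from 2.10 ± 0.310 to 0.705 ± 0.129 CPM, opposite to the rises of SGK1 and FKBP5. NR3C1, the glucocorticoid receptor, fell 1.22-fold, to 31.1 ± 0.295 CPM.

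Genes changed at least 2-fold often lay beside others changed in the same direction. DTX1 was followed, 3' of it on chromosome 12, by RASAL1 (113098819 to 113136239, minus strand), which fell 8.19-fold from 29.9 ± 0.673 to 3.64 ± 0.421 CPM, and near IGF1R lay the long non-coding RNA LUNAR1 (chromosome 15, 99028538 to 99031053), which fell 5.64-fold. Of 646 such genes entered in this test, 203 had another of the same direction within 100 kb, against at most 96 in 1000 permutations matched on expression and coding status (p = 0.001, the smallest they can give), which argues against placement by chance. Without overlapping pairs the number was 156 against at most 85, and without pairs related by symbol, by receptor segment or by a shared transcript stretch of 31 bases it was 106 against at most 72, so reads shared between such genes do not account for all of it. Among protein-coding pairs left after these steps it was 55 against at most 46, so single units counted as several non-coding genes do not account for all of it. Reads running past the end of 1 coding gene into the next were not removed by any step, and use of the strand is not given. A candidate explanation is regulation of neighbours by shared elements, which was not tested.

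The small shifts of the ribosomal protein and mitosis lists could come from a trend of fold change with gene length or GC content. After a length correction the medians were -0.24 (-0.2353) and 0.38 (0.3802), and after a GC correction -0.23 (-0.2304) and 0.39 (0.3912), against -0.23 and 0.39 without. The length was that of the gene in the deposited table (5894 for RPS3, 3667 for DLGAP5). A trend with the length of the expressed transcripts was therefore not tested. After these corrections the ribosomal proteins fell in 69 and 71 of 75 members, and the mitosis genes rose in 34 of 34 after both. This argues against a trend with GC content or with that gene length as the whole cause. A response to compound E is consistent with these values, as a hypothesis only.

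The spread between replicates was small, with a biological coefficient of variation of 2.72%. In genes with a mean of at least 5000 counts, the chi-square over its degrees of freedom was at least 5.52 in each of the 6 pairs of replicates. This argues against 1 library sequenced again with counting noise alone. Whether small differences between runs of 1 library could give such values was not tested. Separate libraries from 1 culture and separate cultures cannot be told apart, since the labels do not say which were used. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many called genes, 1 as many at 2-fold and 1 as many lists, the real split each time, with 6484, 649 and 11. The other splits gave 0 called genes, 0 at 2-fold and 4 to 8 lists by edgeR and camera (210 to 304 genes at an unadjusted p under 0.05). Each of them put libraries of both treatments in both groups, so the treatment effect lay partly within the groups and partly between them. Their counts therefore do not show what would be called without an effect, and 10 splits are too few for a share under 0.05.

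The amino acid response list held some tRNA synthetases, and a hypothesis formed on seeing it was that the cytosolic enzymes fell and the mitochondrial ones did not fall alike. Among 16 cytosolic synthetase genes in no fixed list 13 fell and 0 rose, with a mean log2 fold change of -0.58 ± 0.46 (SD over genes), and among 17 mitochondrial ones 4 fell and 3 rose, with a mean of -0.05 ± 0.16. The difference of -0.53 had a 2-sided permutation p of 7e-05 over 1e+05 resamples, with genes as the units, which are not independent replicates. A lower activity of ATF4, whose own mRNA fell by 1.06 on the log2 scale, may link these falls, and its protein was not measured here.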
